A study of Mus musculus with 5 samples.

How the data were processed

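Gene expression was measured on 2-colour arrays in lungs of 129svJ mice, an inbred strain, treated with bleomycin, an antitumour antibiotic that cleaves DNA and is widely used to injure the lung and provoke fibrosis in mice. Per the labels, each of the 5 arrays carried amplified RNA from the lungs of 1 bleomycin-treated mouse in channel 1 and pooled, amplified lung RNA of control mice of the strain in channel 2. The 5 arrays form 1 group, with mice 1 to 5 as its replicates. Dose, route, time after treatment, sex, the number of mice in the pool, the dyes, the scanner and the way the ratios were normalized are not given in the sources used here.

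The deposited values are 1 log ratio per feature and array, and they were taken as log2 ratios. No source names the log base. A base of 10 is unlikely, since the lowest value, −5.74, would then exceed the range of a 16-bit scanner. The scanner is not given, so that range is an assumption. A natural logarithm is not ruled out, and every fold given here would then be larger. The deposited medians of arrays 1 to 5 were 0.011, 0.012, 0.015, 0.026 and 0.014, so the authors' values were already centred near 0, and each array was centred on its median again. No scanner intensities were used here, so signal over background is unknown and the number of arrays limits the precision.

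The direction of the ratio is not settled. The labels name the bleomycin mouse first and the pool second, which would make the ratio mouse over pool, but they give no dyes. The rule fixed before the data were examined was to read positive values as higher in the bleomycin mouse only if the values did not oppose that reading. They were judged to oppose it, since chemokine, macrophage and cell cycle genes lay mostly below 0 and alveolar and endothelial genes mostly above 0, although Postn and Acta2, genes of matrix and myofibroblasts, lay above 0. Sizes and the side of 0 are therefore given without saying which of mouse and pool was higher. All arrays ran the same way, with Pearson's r across genes between 0.73 and 0.86 for every pair.

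Of 17280 features, 2809 had no value on any array. Features with values on at least 4 of the 5 arrays were kept, which left 10702. Gene symbols came from the platform's annotation, which gave 1 symbol to 14722 features, several to 1 and none to 2557. Symbols were updated through the gene identifiers of 14445 of the 14723 annotated features with a RefSeq table of the GRCm38.p6 assembly, of which no coordinates are printed because no source names a build. Features of 1 symbol were averaged, and features without a single symbol stayed as they were, which gave 10081 genes and unnamed features, 9039 of them with a symbol. Of 462 genes with several features, 46 had features that passed the test on both sides of 0.

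The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept-only linear model with empirical Bayes moderation, two-sided, Benjamini-Hochberg adjustment over all 10081), and adjusted p-values under 0.05 are called past the threshold. The pool counts as 1 control sample, so this test leaves out the spread between control mice. With no dye swap in the labels, gene-specific dye bias does not cancel. An exact sign-flip test of 5 arrays cannot go below p = 0.0625, so the p-values rest on the model. On simulated data with 10081 genes, of which 200 were changed in each of 20 runs, the procedure recovered 91.05% of those changed 1.5-fold and 99.55% of those changed 2-fold, and 4.72% of its calls were false. In 50 further runs nothing was changed, but the shared pool deviated like 1 mouse would. The test then called a median of 2066.5 genes, and at most 51 of them reached 2-fold. With the pool counted as 1 control mouse with the spread of the bleomycin mice, an alternative chosen after seeing the data, the same runs gave a median of 0 calls and at most 2.

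Before the data were examined, 36 gene lists for cell types and processes of lung were fixed, 2 of them for checks (house-keeping and sex-linked genes). The other 34 had at least 5 measured members each and were tested with limma's camera on the moderated statistics (two-sided, against all other named genes, preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 34 lists). Beside it stand camera with a correlation estimated from the arrays, negative estimates being set to 0, and fry. The latter tests whether members move on balance one way and compares the list with no other genes. In the simulated data, where genes were drawn independently of each other, 4.12% of unchanged lists had p under 0.05. Correlations estimated from the arrays were 0.19 for macrophages and 0.208 for cell cycle, but −0.0261 for endothelium and 0.000952 for ribosomal proteins. The simulated rate therefore cannot show how often camera errs on lists with correlated members.

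Named genes followed a rule fixed at the same point. It took the 10 genes farthest from 0 on each side among those past the threshold with every measured array on 1 side. For each list it took up to 3 members past the threshold with the smallest p on the list's majority side and 1 on the other side. Col1a1, Col3a1, Fn1, Tnc, Timp1, Spp1, Acta2, Tgfb1, Sftpc, Scgb1a1 and Cdkn1a were always included. Fn1, Spp1 and Timp1 are not analysed here, since no feature carried the symbol Fn1 or Spp1 in the annotation used and that of Timp1 had no value. The alternatives were values without centring, scaling and quantile normalization between arrays, other minimum numbers of arrays, array weights, a robust variance prior, a plain one-sample test per gene, a minimum fold of 1.2, 1 value per feature, the leaving out of each mouse in turn, ranks for the lists, Spearman's rho for the agreement between arrays, and the pool counted as 1 control mouse. Figures were drawn with matplotlib 3.10.9.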

Results

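Lung expression profiles of 5 bleomycin-treated 129svJ mice were each measured against 1 common pool of control lung RNA. Arrays 1 to 5 held values for 11350, 11951, 12082, 12083 and 11639 of 17280 features. The standard deviation of the deposited log2 ratios was 0.59, 0.49, 0.53, 0.52 and 0.51 on the arrays in that order. Across genes, the 5 arrays correlated with a median Pearson's r of 0.813, from 0.732 to 0.857 over the pairs. Genes are not independent replicates and all arrays share the pool, which adds to each of these correlations. In simulated arrays without any change but with a shared pool that deviated like 1 mouse, the median r was 0.503. The median covariance was 0.0449 there, against an observed median covariance of 0.244. These simulated values follow from the spread given to the pool, and the runs held no shared dye bias. The gap therefore cannot tell a response from dye bias or a wider departure of the pool.

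The comparison of bleomycin-treated lungs with the control pool asks which genes differ in expression between injured and control lung. Among genes past the threshold, those of macrophages, chemokines, dividing cells, interferon response and fibrillar matrix lay mostly on the negative side of the ratio. In the matrix list, 17 lay below 0, 5 lay above 0 and 11 did not pass. Those of alveolar epithelium, club cells and endothelium lay mostly on the positive side. These lists passed camera with its preset correlation. With an estimated correlation chemokines, club cells and endothelium passed (adjusted p = 0.00145, 0.0454 and 0.00145), and the others did not, at adjusted p from 0.145 to 0.283. For endothelium the estimate was negative and set to 0, which is laxer than the preset. The largest ratio that was alike in all mice belonged to Sprr1a, a cornified envelope precursor induced in stressed epithelia, at −4.31 ± 0.25 (SD, n = 5 mice; a 19.8-fold difference). On the other side stood Ogn, the matrix proteoglycan osteoglycin, at 2.84 ± 0.23 (a 7.15-fold difference). The sources do not settle whether a negative value means more RNA in the bleomycin mouse or in the pool, and the values were judged to oppose the order of the titles, so only the side of 0 is given. Folds assume log2 and would be larger if the deposited values were natural logarithms.

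By limma with Benjamini-Hochberg adjustment, 5002 of 10081 genes and unnamed features passed the threshold, 2406 below 0 and 2596 above 0. The median size of their log2 ratios was 0.44, and 564 of them differed at least 2-fold, 237 below 0 and 327 above 0. All measured arrays lay on 1 side for 4734 of the 5002. Because the pool was the same on every array, a chance departure of the pool counts as a difference in this test. With the pool counted as 1 control mouse, an alternative chosen after seeing the data, 495 passed, 208 below 0 and 287 above 0, and 311 of them differed at least 2-fold. Of 142 named genes past the threshold, 71 passed in that setting. Among the genes that the rule for named genes took and the text describes, those it left out were Tnnc2, Myh8, Myh2, Atp2a1, S100a4, Ppia, Prdx1, Mmp14, Tnc, Cxcl15, Nupr1, Bbc3, Jchain, Mmp8, Gzmb, Rpl10a, Scgb1a1, Acta2, Cxcl12, Irgm1, Nr1d1, Hmgb2, Hp, Lama4, Fabp1, Cd36, Scd1, Des, Nppb, Ccl5, Ifi30, Tagln, Satb1 and Fdps. Myh2, Mmp8, Gzmb, Rpl10a, Scgb1a1, Ccl5, Ifi30, Tagln, Satb1 and Fdps also missed the threshold when a difference of at least 1.2-fold was required.

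After Sprr1a, the lowest means among genes past the threshold that were below 0 in all mice belonged to Tnnc2, Chl1, Myh8, Myh2, Atp2a1, Retnla, S100a4, Cxcl1 and Serpina3n. Chl1, a neural cell adhesion molecule, stood at −3.70 ± 0.33 (SD, n = 5; adjusted p = 8.87e-06). Retnla, a product of alternatively activated macrophages and injured airway epithelium, stood at −2.87 ± 0.45, and Cxcl1, a neutrophil-attracting chemokine, at −2.70 ± 0.58. Serpina3n, an acute-phase protease inhibitor, was at −2.70 ± 0.39, and S100a4, a calcium-binding protein of fibroblasts and macrophages, at −2.76 ± 0.73. The remaining 4 are skeletal muscle genes with a wide spread between mice. Tnnc2, the fast troponin C, averaged −3.74 ± 2.34 (adjusted p = 0.00739) and the perinatal myosin Myh8 −3.44 ± 2.08 (adjusted p = 0.00645). The fast myosin Myh2 averaged −3.03 ± 2.61 (adjusted p = 0.0255) and the calcium pump Atp2a1 −2.91 ± 1.2 (adjusted p = 0.00127). Not every mouse was far below 0: in mouse 3, Tnnc2 stood at −0.035 and Myh8 at −0.228. Myh2 stood at −0.236 in mouse 3 and −0.226 in mouse 4. Myh2 missed the threshold without mouse 1, 2 or 5 (adjusted p = 0.0649, 0.0812 and 0.0832). Its mean was −2.35 without mouse 1 and −3.73 without mouse 3 or mouse 4, and without mouse 3 the means of Tnnc2 and Myh8 were −4.66 and −4.24. With a plain one-sample test in place of limma's moderated one, Tnnc2, Myh8 and Myh2 missed it too (adjusted p = 0.0567, 0.053 and 0.11).

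Farthest above 0 after Ogn were Tspan13, Tnks2, Pecam1, Sftpa1, Acbd5, Smg1, Tmem100, Kcnk2 and Fmo2. The tetraspanin Tspan13 stood at 2.67 ± 0.22 (SD, n = 5; adjusted p = 8.87e-06). Pecam1, the adhesion molecule of endothelial junctions, stood at 2.45 ± 0.30 (adjusted p = 2.32e-05) and Tmem100, an endothelial gene downstream of BMP signalling, at 2.32 ± 0.30. Sftpa1, surfactant protein A of type 2 cells and club cells, was at 2.41 ± 0.30 (adjusted p = 2.33e-05), and the flavin monooxygenase Fmo2 at 2.30 ± 0.35. The tankyrase Tnks2 stood at 2.53, the peroxisomal protein Acbd5 at 2.37, the kinase Smg1 of nonsense-mediated decay at 2.36 and the potassium channel Kcnk2 at 2.31. All 10 genes of this side also passed with the pool counted as 1 control mouse.

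**Figure D1:**
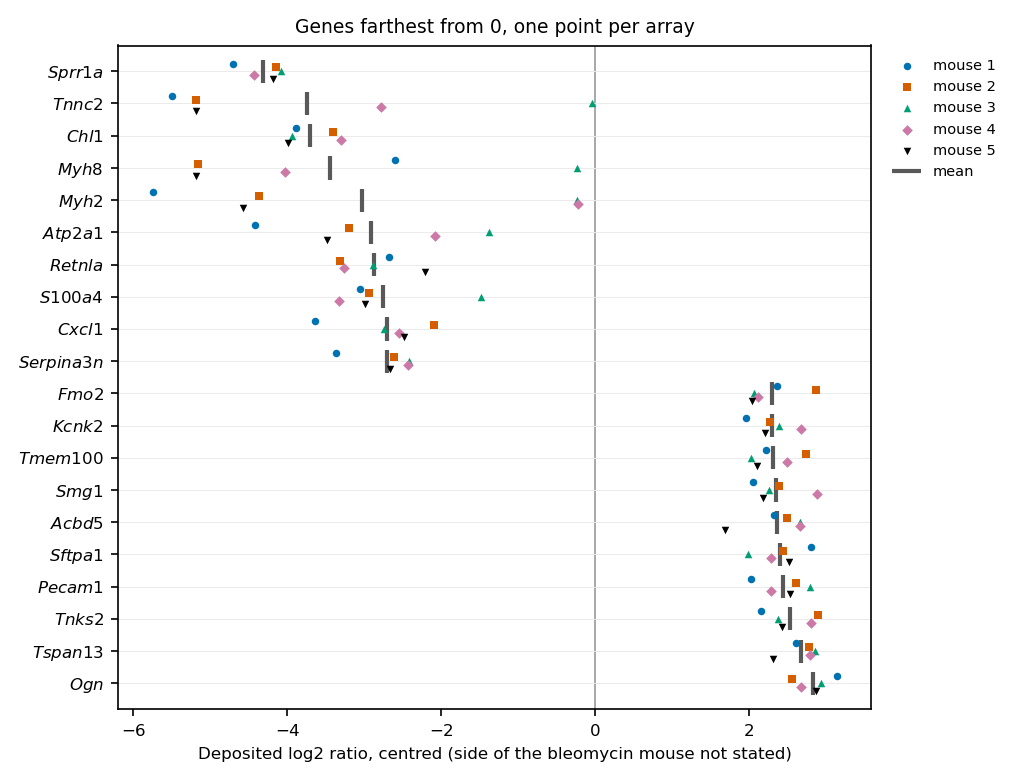
Centred deposited log2 ratio (horizontal axis) of the 10 genes farthest from 0 on each side, with 1 point per mouse and a vertical bar for the mean of 5 mice. The points of Sprr1a lie between −4.70 and −4.09, while those of the muscle gene Tnnc2 run from −5.50 to −0.04.

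Of the 34 gene lists fixed beforehand, 12 stood apart from the other named genes by camera with its preset correlation, 7 below 0 and 5 above 0. With an estimated correlation 4 of them passed, namely chemokines and ribosomal proteins below 0 and club cells and endothelium above 0. By fry, which asks only whether a list's members lie on balance on 1 side, 24 lists passed. Counting the pool as 1 control mouse left fewer members past the threshold. Below 0 these were 7 macrophage, 6 chemokine, 6 cell cycle, 2 interferon response, 6 oxidative phosphorylation and 5 ribosomal protein genes, with 0 above. Above 0 they were 2 type 2 alveolar, 3 type 1 alveolar, 3 club cell and 1 fatty acid oxidation genes, with 0 below. Matrix genes numbered 5 below and 2 above, and endothelial genes 2 below and 3 above.

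Lists of chemokines, macrophages and interferon response lay below 0. Of 41 measured genes of chemokines, cytokines and their receptors, 24 were below 0, 1 was above 0 and 16 did not pass (adjusted over the list alone, 25 below and 1 above). The list averaged −0.58 (SD between mice 0.10; adjusted p = 1.36e-05, and adjusted p = 0.00145 with an estimated correlation). Examples were the macrophage chemokine Ccl3 at −2.54 ± 0.32, the chemokine Ccl9 at −1.15 ± 0.13 and the cytokine Tnf at −1.27 ± 0.21, against Cxcl12, a stromal chemokine, at 0.72 ± 0.34. Of 33 macrophage and monocyte genes, 24 were below 0 and 3 above 0 (adjusted over the list alone, 24 and 4), with a list mean of −0.83 (SD 0.23; adjusted p = 1.36e-05, but adjusted p = 0.145 with an estimated correlation). The complement component C1qb stood at −2.68 ± 0.23 and the lectin receptor Clec4n at −1.94 ± 0.14, whereas the fatty acid transporter Cd36 stood at 1.46 ± 0.51. Of 27 interferon response genes, 14 were below 0 and 3 above 0 (adjusted over the list alone, 15 and 3), with adjusted p = 0.000884 for the list but adjusted p = 0.149 with an estimated correlation. Ifitm3, which restricts virus entry, was at −2.01 ± 0.27 and the GTPase Irgm1 at 0.81 ± 0.27.

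Other immune lists did not stand apart from the remaining genes. Neutrophil genes had 2 of 10 on each side (adjusted over the list alone, 1 below and 2 above; adjusted p = 0.481), with a median of −0.12 but a mean of 0.00024. Their examples were the acute-phase protein haptoglobin, Hp, at 1.00 ± 0.32 and the neutrophil collagenase Mmp8 at −0.42 ± 0.42, whose call (adjusted p = 0.049) was lost without mouse 1, 2, 3 or 5, with adjusted p from 0.1 to 0.141. It was also lost without centring (adjusted p = 0.0573) and with features on at least 3 arrays (adjusted p = 0.0531). T and NK cell genes had 3 of 20 below and 4 above 0 (adjusted over the list alone, 3 and 4; adjusted p = 0.807), among them granzyme B, Gzmb, at 0.29 ± 0.12. B and plasma cell genes had 7 of 16 below and 3 above (adjusted over the list alone, 8 and 3; adjusted p = 0.163), with the immunoglobulin J chain, Jchain, at −0.70 ± 0.09 on 4 arrays. Genes of mast cells, basophils and eosinophils had 3 of 8 below and 2 above (adjusted over the list alone, 3 and 2; adjusted p = 0.594). Of MHC class II genes 2 of 8 were below 0 and 0 above (adjusted over the list alone, 2 and 0; adjusted p = 0.17). Of MHC class I and immunoproteasome genes, 6 of 14 were below and 2 above (adjusted over the list alone, 6 and 2; adjusted p = 0.187). Complement and coagulation genes had 9 of 26 below, including the complement factor Cfb at −1.46 ± 0.25, and 4 above (adjusted over the list alone, 9 and 4; adjusted p = 0.17).

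Of 38 measured cell cycle genes, 27 were below 0, 5 above 0 and 6 did not pass (adjusted over the list alone, 27 below and 6 above). The list averaged −0.52 (SD between mice 0.10; adjusted p = 1.36e-05, but adjusted p = 0.149 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, stood at −1.95 ± 0.25, the spindle protein Tpx2 at −1.22 ± 0.20 and the histone H2ax at −1.12 ± 0.12, while the chromatin protein Hmgb2 stood at 0.97 ± 0.34. The p53 and DNA damage list was divided, with 7 of 18 below and 6 above (adjusted over the list alone, 7 and 7; adjusted p = 0.724). Its p53 targets Cdkn1a, an inhibitor of cyclin-dependent kinases, and Ccng1, cyclin G1, stood at −1.61 ± 0.13 and −1.77 ± 0.21, the cell death gene Bbc3 at −0.74 ± 0.24 and the stress gene Trp53inp1 at 1.23 ± 0.16 on 4 arrays.

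Genes of the matrix list past the threshold were mostly below 0. The matrix proteoglycan Ogn, at 2.84 ± 0.23, was not on that list. Of 33 measured genes of fibrillar collagens and matrix glycoproteins, 17 were below 0, 5 above 0 and 11 did not pass (adjusted over the list alone, 17 and 5). The list averaged −0.29 (SD between mice 0.08; adjusted p = 0.0209, but adjusted p = 0.283 with an estimated correlation, and adjusted p = 0.0812 when features on at least 3 arrays were kept). The proteoglycan versican, Vcan, stood at −2.52 ± 0.21 (−1.85 with features on at least 3 arrays), the growth factor Igf1 at −1.91 ± 0.21, the fibrillar collagen Col3a1 at −1.29 ± 0.15 and the glycoprotein tenascin C, Tnc, at −0.94 ± 0.27. Periostin, Postn, also a matrix glycoprotein, stood at 1.07 ± 0.14. Col1a1, the main collagen of scar tissue, averaged 0.02 ± 0.50 (adjusted p = 0.916) and turned to −0.18 without mouse 4. Basement membrane genes had 4 of 15 below and 5 above (adjusted over the list alone, 5 and 5; adjusted p = 0.857), including Col15a1 at −1.41 ± 0.16 and the laminin chain Lama4 at 1.08 ± 0.34. Of proteases and inhibitors of matrix turnover, 10 of 21 were below and 4 above (adjusted over the list alone, 10 and 5; adjusted p = 0.17), with the membrane protease Mmp14 at −1.01 ± 0.31 and the inhibitor Timp3 at 0.97 ± 0.17. TGF-beta signalling had 2 of 20 below and 11 above (adjusted over the list alone, 3 and 11; adjusted p = 0.104), including the latency protein Ltbp4 at 1.30 ± 0.31. Tgfb1 itself averaged 0.01 ± 0.11 (adjusted p = 0.924) and turned to −0.03 without mouse 4. Smooth muscle and myofibroblast genes had 2 of 8 on each side (adjusted over the list alone, 2 below and 3 above; adjusted p = 0.481), with smooth muscle actin, Acta2, at 0.71 ± 0.33 (adjusted p = 0.00288). The list mean was −0.26, −0.20, 0.52, 0.44 and 0.08 in mice 1 to 5. The median log2 ratio of skeletal muscle markers was also lowest on the arrays of mice 1 and 2 and highest on that of mouse 3. Desmin, Des, a filament of all muscle types, averaged −1.19 ± 0.79 and missed the threshold with the plain one-sample test (adjusted p = 0.0642).

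Lists of alveolar, club cell and endothelial genes lay above 0. Of 17 type 2 alveolar genes, 9 were above 0 and 1 below (adjusted over the list alone, 9 and 1), with a list mean of 0.72 (SD between mice 0.25; adjusted p = 0.00454, but adjusted p = 0.149 with an estimated correlation). The lipogenic enzymes Scd1 and Fasn stood at 1.79 ± 0.50 and 1.502 ± 0.19, and the lung chemokine Cxcl15 at −0.91 ± 0.26. Surfactant protein C, Sftpc, averaged −0.27 ± 1.24 (adjusted p = 0.612) and turned to 0.23 without mouse 3. Of 15 type 1 alveolar genes, 9 were above 0 and 0 below (adjusted over the list alone, 11 and 0), with a list mean of 0.82 (SD 0.23; adjusted p = 0.000563, but adjusted p = 0.149 with an estimated correlation). Sema3e stood at 1.60 ± 0.27 and caveolin 1, Cav1, at 1.11 ± 0.17 on 4 arrays.

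Of 30 club cell and xenobiotic metabolism genes, 20 were above 0 and 3 below (adjusted over the list alone, 22 and 3), with a list mean of 0.62 (SD 0.12; adjusted p = 0.000285, and adjusted p = 0.0454 with an estimated correlation). The flavin monooxygenase Fmo1 stood at 2.28 ± 0.16, carbonyl reductase 2, Cbr2, at 2.14 ± 0.52, the club cell secretory protein Scgb1a1 at 0.47 ± 0.16 and the stress gene Nupr1 at −0.83 ± 0.25. With the pool counted as 1 control mouse, the members that passed were the enzymes Fmo1, Fmo2 and Cbr2, and Scgb1a1 did not pass. Ciliated cell genes had 3 of 8 above and 1 below (adjusted over the list alone, 3 and 1; adjusted p = 0.387). Of 33 endothelial genes, 19 were above 0 and 5 below (adjusted over the list alone, 21 and 5), with a list mean of 0.47 (SD 0.02; adjusted p = 0.0031, and adjusted p = 0.00145 with an estimated correlation). Besides Pecam1 and Tmem100, the angiopoietin receptor Tek stood at 1.54 ± 0.24, and Ly6c1, a surface antigen also found on monocytes, at −1.54 ± 0.16.

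**Figure D2:**
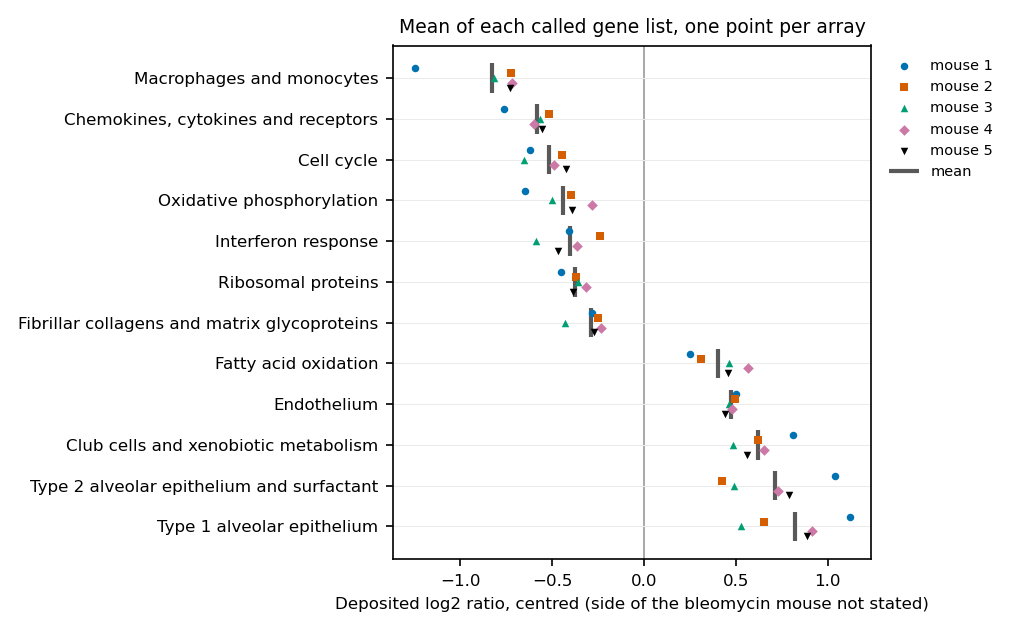
Mean centred log2 ratio (horizontal axis) of the 12 gene lists that passed camera with its preset correlation, with 1 point per mouse and a vertical bar for the list mean. Macrophage genes lie lowest at −0.83 and type 1 alveolar genes highest at 0.82, and for each of these lists the 5 mice lie on 1 side of 0.

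Genes of energy metabolism and translation divided by pathway. Of 43 oxidative phosphorylation genes, 24 were below 0 and 2 above (adjusted over the list alone, 27 and 3), with a list mean of −0.44 (SD 0.14; adjusted p = 7.3e-05, but adjusted p = 0.145 with an estimated correlation). The cytochrome c oxidase subunit Cox6c stood at −1.504 ± 0.20 and the complex III subunit Uqcrh at −1.25 ± 0.17. Of 45 ribosomal protein genes, 23 were below 0 and 4 above (adjusted over the list alone, 24 and 5), with a list mean of −0.38 (SD 0.05; adjusted p = 0.000228, and adjusted p = 3.74e-05 with an estimated correlation). Rpl21 stood at −1.201 ± 0.13 on 4 arrays and Rpl10a at 0.40 ± 0.16. Of 26 fatty acid oxidation genes, 12 were above 0 and 0 below (adjusted over the list alone, 12 and 0), with a list mean of 0.40 (SD 0.13; adjusted p = 0.00454, but adjusted p = 0.179 with an estimated correlation). The dehydrogenase Acadm stood at 1.57 ± 0.33 and the fatty acid binding protein Fabp1 at 1.45 ± 0.44. Ratios across all named genes were weakly related to the genomic span of the gene (Spearman's rho of 0.18 over 8890 genes). Glycolysis and hypoxia genes had 7 of 22 below and 4 above (adjusted over the list alone, 8 and 4; adjusted p = 0.302), with pyruvate kinase, Pkm, at −1.40 ± 0.23. Cholesterol synthesis genes had 5 of 16 below and 2 above (adjusted over the list alone, 5 and 2; adjusted p = 0.515), with a median of −0.03 but a mean of 0.03.

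Lists of oxidative stress, protein folding and immediate early genes had members past the threshold on both sides. Oxidative stress genes had 8 of 24 below and 9 above (adjusted over the list alone, 10 and 9; adjusted p = 0.807), with glutathione reductase, Gsr, at 1.91 ± 0.43, catalase, Cat, at 1.195 ± 0.28 and peroxiredoxin 1, Prdx1, at −1.08 ± 0.28. Of the genes for protein folding in the endoplasmic reticulum, 7 of 30 were below and 11 above (adjusted over the list alone, 7 and 11; adjusted p = 0.362), with Herpud1, a component of endoplasmic reticulum-associated degradation, at 1.93 ± 0.28. Immediate early genes had 7 of 19 below and 9 above (adjusted over the list alone, 7 and 9; adjusted p = 0.741), with the phosphatase Dusp1 at 2.08 ± 0.39 and the cytokine signal inhibitor Socs3 at −1.89 ± 0.37. Circadian clock genes had 0 of 10 below and 5 above (adjusted over the list alone, 0 and 5; adjusted p = 0.104), with the repressor Nr1d1 at 0.93 ± 0.29.

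Skeletal muscle markers varied between mice. Cardiac and skeletal muscle genes had 9 of 29 below and 8 above (adjusted over the list alone, 10 and 8; adjusted p = 0.807), and the list mean of −0.48 had an SD between mice of 0.71. Relative to the mean of the other named genes, the list moved from −0.504 to −0.297 without mouse 1. The median of 13 skeletal members was −3.29, −2.03, −0.03, −0.33 and −1.73 in mice 1 to 5. That of 9 cardiac members was 0.34, 0.41, 0.63, 0.68 and 0.74, with the cardiac myosin Myh6 at 1.94 ± 0.39. Adipose and mesothelial genes had 2 of 13 below and 6 above (adjusted over the list alone, 2 and 6; adjusted p = 0.302), with Ucp1, the uncoupling protein of brown fat, at 1.98 ± 0.48. Red blood cell genes had 2 of 9 on each side (adjusted over the list alone, 2 and 2; adjusted p = 0.741), with the blood group gene Rhd at −2.21 ± 0.28 and the membrane protein Epb42 at 1.39 ± 0.18.

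**Figure D3:**
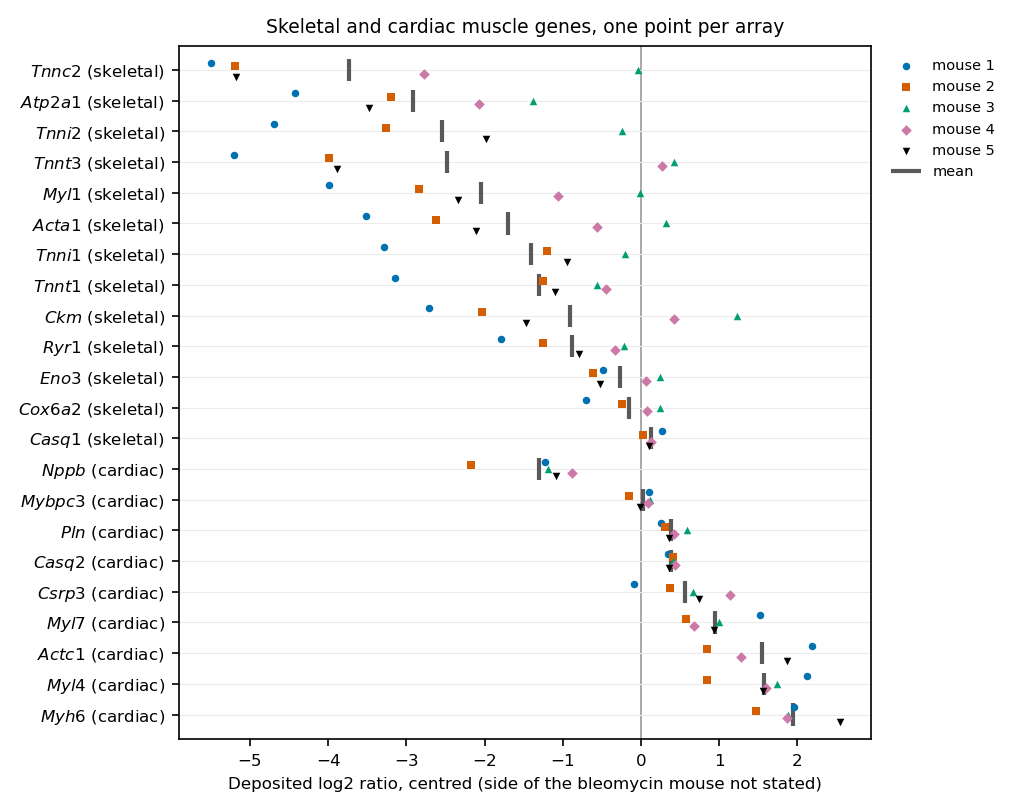
Centred log2 ratio (horizontal axis) of 13 skeletal and 9 cardiac muscle genes, leaving out list members found in both, with 1 point per mouse and a vertical bar for the mean. Skeletal genes such as Tnni2 reach −4.69 in mouse 1 and stay near −0.24 in mouse 3, while the cardiac gene Myh6 lies between 1.47 and 2.55.

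Of 12 house-keeping genes used as a check, 4 were below 0 and 4 above (adjusted over the list alone, 4 and 4), with a median of −0.02. Cyclophilin A, Ppia, stood at −1.51 ± 0.47 and the elongation factor Eef1a1 at 1.496 ± 0.24, while Gapdh averaged −0.02 ± 0.84 over its 14 features, from −1.37 in mouse 1 to 0.95 in mouse 4, and turned to 0.31 without mouse 1. Sex-linked genes had 4 measured members, too few for a test. Xist, expressed from the inactive X chromosome, averaged 0.18 ± 0.19 (adjusted p = 0.0841) and 0.12 without mouse 1, Eif2s3x 0.35 ± 0.20, Kdm6a 1.04 ± 0.55 and the Y-linked gene Eif2s3y −0.30 ± 0.14 (adjusted p = 0.00809). The first was not past the threshold, and the others were.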

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

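The tests of explanations in this part were chosen after the data were seen. In 183 sets of values per mouse, the 145 named genes among them, 14 had 1 mouse far from the other 4, where chance alone gives about 9.15. Mice 1 to 5 were the one apart in 3, 4, 3, 2 and 2 cases. On the log2 scale, mouse 3 stood apart for S100a4 at −1.49 (the nearest other mouse at −2.94), for Irgm1 at 0.35 (0.84) and for the mean of the matrix list at −0.43 (−0.29). Mouse 1 stood apart for Serpina3n at −3.37 (−2.66), Ifi30 at −1.05 (−0.44; mean −0.44 with and −0.29 without mouse 1) and the mean of the macrophage list at −1.25 (−0.82). Mouse 2 stood apart for Nppb at −2.17 (−1.22), Col3a1 at −1.02 (−1.34), Gzmb at 0.082 (0.306) and Herpud1 at 1.44 (1.99). Mouse 4 stood apart for Ccl5 at −1.44 (−0.62) and the mean of the protease list at −0.10 (−0.32). Mouse 5 stood apart for Rpl10a at 0.68 (0.35) and Cpe at 1.16 (1.42).

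By camera with its preset correlation, chemokine, macrophage, cell cycle and matrix lists lay below 0 and alveolar, club cell and endothelial lists above 0. Chemokines and club cells also passed with an estimated correlation, as did endothelium, where the estimate was laxer than the preset. An injury response read through a ratio of control pool over bleomycin mouse may underlie these sides of 0, but its test decides nothing. Of 9 lists with a textbook direction in injured lung, 8 passed on the side of that reading and 0 on the other, yet these 9 were picked after their sides were seen. TGF-beta signalling, smooth muscle and neutrophil lists, left out of the 9, did not pass camera (adjusted p = 0.104, 0.481 and 0.481). By fry, TGF-beta signalling did pass (adjusted p = 0.00214), on the side of 0 opposite to the matrix list, with 11 members above 0 and 2 below. Smooth muscle and neutrophil lists did not pass by fry either. Gene-specific dye bias shared by all arrays stays open as well, since the 89.3% of 84 macrophage, chemokine and cell cycle genes past the threshold that lay below 0 (47.6% of all named genes past it) come from lists picked for that side. A control pool that departs from other control lungs cannot be told apart from a response, because no control lung was measured on its own, and 495 genes and unnamed features passed with the pool given the spread of 1 mouse.

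Skeletal muscle genes lay far below 0 in mice 1, 2 and 5 and near 0 in mouse 3, with the abundant Acta1 and Ckm at −3.52 and −2.71 in mouse 1 and 0.32 and 1.23 in mouse 3. The median of the skeletal members moved by 3.26 between arrays and that of the cardiac members by 0.403, which tests no array-wide shift because each array was centred on its median. The 9 skeletal members measured on all arrays ordered the mice nearly alike (Kendall's W of 0.901), but this was seen before it was tested and decides nothing between the explanations left. Skeletal muscle RNA may have been carried into some of the samples, and a change of muscle genes within the lung would give the same shared order, so they cannot be told apart.

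Ribosomal protein and oxidative phosphorylation lists lay below 0 on all 5 arrays. Removing the trend of the ratio with the genomic span of the gene left the oxidative phosphorylation median at −0.352 (bootstrap SE 0.077, and −0.393 before), so that trend did not take up the whole shift there. The SE treats members as independent, though their estimated correlation was 0.126, so it may be too small. The ribosomal median went from −0.298 to −0.211 (bootstrap SE 0.091), which leaves a part played by the trend open. A pool of different RNA quality or amplification would act on all 5 arrays alike and cannot be told apart from a response to bleomycin, since every array carried the pool. The response to bleomycin itself stays open and untested.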

How the results depend on the processing

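The pool counted as 1 control mouse was chosen after seeing the data, and the other alternatives before. With a minimum fold of 1.2, 1847 genes and unnamed features passed, 811 below 0 and 1036 above 0. With the pool counted as 1 control mouse 495 passed, 208 below 0, 287 above 0 and 311 at least 2-fold, and 71 named genes kept their call, all by construction of a stricter test. Lists past the threshold numbered 4 with an estimated correlation and 24 by fry, against 12. The first allows for correlated members, but for endothelium and ribosomal proteins the estimate lay under the preset, which made it laxer. The second compares with no other genes.

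Under other centring, scaling, filters, weights and priors, and without each mouse in turn, the count of calls ran from 4106 to 5119. With 1 value per feature 5311 of 10702 features passed, and the plain one-sample test gave 3866 calls. All these counts stayed within 1.5 times of 5002. Of the calls, 4857 of 5021 without centring and 4021 of 4106 without mouse 3 were also among the 5002. No named gene past the threshold and no list past it changed its side of 0 under any alternative. Named genes lost their call in 24 cases with the minimum fold, 11 with the plain test, and 4, 5, 3, 0 and 3 without mice 1 to 5, among them Tagln, Satb1 and Mmp8 without mouse 1, 2 or 3, Fdps without mouse 2 and Ifi30 without mouse 5. The 12 called lists kept their call without each mouse, and the matrix list lost it with features on at least 3 arrays. The cause was not tested. The signal over background is unknown, so a dim feature cannot be told from a bright one.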

Other observations

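Cidea, Ucp1 and Nppb come from the rule for named genes, and the other genes and features in this part were chosen after their values were seen. A few genes were picked for a wide spread between mice, with no list or enrichment test behind them. In mice 1 to 5, Lor, loricrin of the cornified envelope, stood at −0.50, −4.23, 0.09, 0.07 and −3.92. Lce1a1, also of the cornified envelope, stood at −1.04, −4.80, −0.34, −0.26 and −5.08, and the basal keratin Krt5 at −0.24, −2.49, −0.13, 0.17 and −1.97. None of these 3 passed the threshold (adjusted p = 0.0946, 0.0517 and 0.0971).

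Single muscle and fat genes stood on different sides. The atrial light chains Myl4 and Myl7 stood at 1.57 ± 0.46 and 0.95 ± 0.37 (SD, n = 5; adjusted p = 0.000361 and 0.00127), and cardiac actin, Actc1, at 1.55 ± 0.60 on 4 arrays (adjusted p = 0.00212). Cidea, a lipid droplet protein of brown fat, stood at 1.00 ± 0.16 (adjusted p = 7.69e-05), beside Ucp1 at 1.98 ± 0.48. The natriuretic peptide gene Nppb stood at −1.31 ± 0.50 and was below 0 in all 5 mice, and sarcolipin, Sln, averaged −0.01 ± 0.07 on 4 arrays (adjusted p = 0.856).

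Other single genes below 0 were the microglia and macrophage marker Aif1 at −2.36 ± 0.34, the chemokine receptor Cx3cr1 at −2.19 ± 0.26, the galectin Lgals1 at −2.21 ± 0.25 and arginase 1, Arg1, at −2.06 ± 1.14 (adjusted p = 2.88e-05, 2.32e-05, 2.16e-05 and 0.00442). The anion exchanger Slc26a4 stood at −2.68 ± 0.37, the peptide hormone Cck at −2.30 ± 0.92 and transthyretin, Ttr, at 2.26 ± 0.45. Among features without a gene symbol, feature 534 stood at −3.81 ± 0.69 and feature 14617 at 1.70 ± 0.17. The median SD between arrays over all genes and unnamed features was 0.156.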
